A study of Rattus norvegicus with 6 samples.

How the data were processed

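RNA sequencing of cultured cells was compared between 2 inbred rat strains, the spontaneously hypertensive rat (SHR) and its normotensive Wistar Kyoto control (WKY). Per the labels' protocols, the proximal aorta of 3-month-old animals was cut into pieces and laid luminal side down in culture wells, and the cells that were called endothelial were grown in endothelial medium with serum and growth supplement before total RNA was taken. Each strain had 3 libraries, which the labels describe as separate samples of a strain; whether each came from its own animal or from separate cultures is stated only as a number per group, so p-values measure the spread between these libraries. The labels put replicates 1 and 2 of each strain in batch 1 and replicate 3 of each strain in batch 2. Sequencing was paired-end with 100 bp reads on a DNBSEQ instrument.

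The authors deposited estimated counts per gene, 1 column per library, not normalized. Per the submitters' processing notes, Bowtie2 2.4.4, RSEM 1.2.28, DESeq2 1.42.1 and the Rnor_6.0 build were named without roles, so which step used which tool is not given in the sources used here. Of the estimated counts, 9% were not whole (tolerance 0.001), as an estimating counter that shares reads between similar genes would give. The counting of strand, overlapping genes and near-identical gene copies is not given in the sources used here, and values of genes with a near-identical copy are therefore uncertain. The second file the authors deposited holds log2 values of the 16770 genes. From the values, the mean of batch 1 and the mean of batch 2 were equal in every gene (largest difference 7.5e-09), and 95.9% of values lay within 0.01 of a regularised log transform of the estimated counts with the batch difference removed, computed here with DESeq2 and limma. How the log2 values were made is inferred from that match and is not given in the sources used here.

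The estimated counts were rounded to whole numbers. Of 16770 genes, 16193 had a count in at least 1 library. Genes were kept for testing with the filterByExpr function of edgeR by strain, which left 12614. Libraries were scaled by TMM factors, which lay between 0.87 and 1.07, and levels are given as CPM of the scaled library. Strains were compared with the quasi-likelihood F-test of edgeR 4.0.16 (glmQLFit with robust dispersion, glmQLFTest) in R 4.3.3, with batch and strain as terms and 3 residual degrees of freedom. The p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p below 0.05. All tests were two-sided. Log2 fold changes are SHR over WKY, and their standard error (SE) was computed from the fold change and the F statistic. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, with the same terms and a preset inter-gene correlation of 0.01, adjusted over the 24 lists with at least 5 measured members. The other 9 of the 33 lists are described by levels and counts alone. Where a p-value is adjusted over the list alone, it covers the tested members of that list, in some lists very few. It is not corrected for the number of lists, so it does not control error across them.

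The design, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. The rule named Igfbp6, which the series title refers to, and Cd36 as a strain check. It added the 8 genes with the largest log2 fold change in each direction among called genes with a mean of at least 5 CPM and no overlap between the libraries of the strains, leaving out genes known only by a locus name, and the 4 members of each list with the smallest adjusted p. Of the 32 called genes 17 met it, and 7 higher and 8 lower genes were named. The lists held 563 genes, of which 525 were found by symbol, 3 by gene identifier and 35 were not matched. A RefSeq gene table of the GRCr8 assembly was used for current gene names only, and 94.1% of identifiers in the estimated count table matched it. Coordinates are not printed, because that assembly differs from the build named in the notes.

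Total counts lay between 18462051 and 19947278 per library, with 14387 to 14997 genes above 0 and 5.69% to 8.87% of counts in the 10 most abundant genes. In a single library 3 counts, the upper limit that a count of 0 allows, corresponded to 0.15 to 0.19 CPM. This floor covers counting error only, since reads were not marked by molecule. Differences between the counts of any 2 libraries were far above sampling noise (chi-square per gene 46.9 to 462), so no library was a duplicate of another.

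The test code was tested on simulated data, in 5 simulations of the comparison of SHR with WKY with a batch term. Each held 12614 genes drawn from the fitted means and dispersions of the 6 libraries, with 200 of them changed. A further short list of genes was raised 2-fold. It is outside the recovered shares given here, and calls of its genes were not counted as false. The quasi-likelihood test recovered 23.6% of genes changed 2-fold, 80.3% of those changed 4-fold and 87.6% of those changed 8-fold, and 7.87% of its calls were false. For the DESeq2 Wald test the shares were 46.3%, 87.5% and 92.1%, with 26.0% of calls false. The values for limma-voom were 17.3%, 79.7% and 87.3%, with 6.48% false.

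Whether replicate numbers pair the libraries was checked from the deviations of each library from its strain mean in log2 CPM. Same-numbered libraries of the strains correlated at 0.30 for number 1, 0.40 for number 2 and 0.66 for number 3, across genes. All were above 0.1, which was the limit set for treating the numbers as pairs, so fits with the replicate number as a block are given beside results that it changes. Libraries of batch 1 with unlike numbers correlated at 0.49 and 0.48, and the difference between replicates 1 and 2 correlated at -0.20 between the strains, so the pairing follows the labelled batch and not the number within it.

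The alternatives were scaling by median-of-ratios or upper-quartile factors, no low-count filter or a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0 or limma-voom in place of edgeR, no batch term, the replicate block, batch 1 alone, each library left out in turn, no robust dispersion, and for lists an estimated correlation, fry, and camera without Igfbp6. Added after the data were seen were limma on the log2 values the authors deposited, the estimated correlation within each other alternative, the share of genes without overlap in other splits of the libraries, and summing the counts of each gene with its numbered copies (current RefSeq symbols of the form gene name, l and a number, which also take in some distinct paralogues such as Sparcl1).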

Results

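Cells grown from aortic explants of WKY and SHR rats, labelled endothelial, were profiled by RNA sequencing to compare the normotensive with the hypertensive strain. There were 3 libraries of each strain, of which 2 belonged to batch 1 and 1 to batch 2. Totals of 18462051 to 19947278 estimated counts per library gave a similar depth in both strains. On the first principal component of log2 CPM, which held 55.0% of the variance, both batch 2 libraries (90.3 for WKY and 90.9 for SHR) lay apart from the batch 1 libraries (-55.2 to -34.9). The second component, with 23.8%, separated the strains, with WKY between 13.9 and 62.5 and SHR between -56.9 and -25.3. Libraries of the same strain and batch correlated at 0.953 to 0.971 across genes, libraries of other strains in the same batch at 0.892 to 0.957, and libraries of the same strain in other batches at 0.832 to 0.856. WKY replicate 2 correlated with SHR replicates 1 and 2 (0.956 and 0.957) as highly as with WKY replicate 1 (0.953).

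The title of the series names insulin-like growth factor-binding protein 6, a secreted protein that binds IGF-II with preference, so its transcript was examined first. Igfbp6 (gene identifier 25641) had 288 ± 150 CPM in WKY and 765 ± 191 CPM in SHR (SD, n = 3 each). Each SHR library (565 to 947 CPM) lay above each WKY library (122 to 413 CPM), and an exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 allows. That test exchanges libraries between batches. Only 5 other splits part the batch 2 libraries as the strains do, so within batches the smallest value would be above 0.1. The fitted difference was 1.40 on the log2 scale (SE 0.47), or 2.63-fold. Within batch 1 it was 1.33 and the ratio of the single libraries of batch 2 was 1.52 on the same scale. It did not pass the edgeR quasi-likelihood test after adjustment over all genes (unadjusted p = 0.0282, adjusted p = 0.329) or adjusted over the list alone (0.109). The DESeq2 Wald test called it, with a log2 fold change of 1.41 (SE 0.46) and an adjusted p of 0.0414, and its adjusted p in the edgeR alternatives with all 6 libraries and the batch term lay between 0.314 and 0.354. In the log2 values the authors deposited, Igfbp6 stood at 12.59 ± 0.53 in WKY and 13.59 ± 0.15 in SHR (SD, n = 3 each). The batch means are equal in those values, so these SDs leave out the batch difference and are not comparable with those in CPM.

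**Figure D1:**
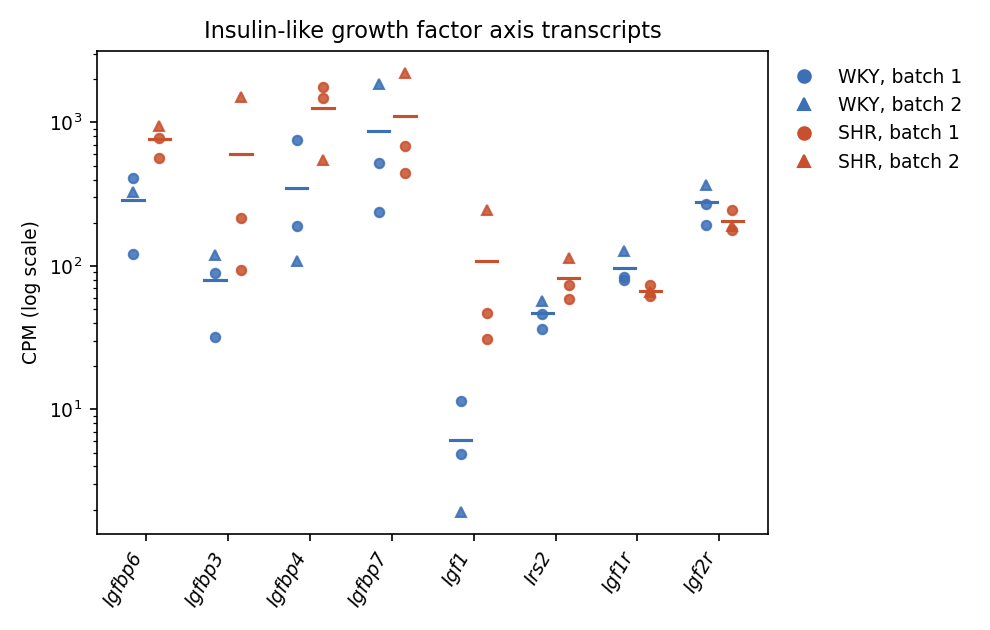
Levels of 8 transcripts of the insulin-like growth factor axis in CPM on a log axis, for each of the 3 WKY and 3 SHR libraries; circles are batch 1, triangles batch 2, and horizontal bars strain means. Igfbp6 lay between 122 and 413 CPM in WKY and between 565 and 947 CPM in SHR, without overlap.

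Of 16 measured members of the insulin-like growth factor axis list, 0 were called by edgeR, over all genes or adjusted over the list alone, while 5 were higher and 1 lower at an unadjusted p below 0.05. DESeq2 called 5, all higher in SHR. Besides Igfbp6 these were Irs2, an adaptor of insulin and IGF receptors (46.6 ± 10.1 CPM in WKY and 81.9 ± 27.8 in SHR), the binding protein gene Igfbp4 (349 ± 349 and 1266 ± 639), the growth factor gene Igf1 (6.06 ± 4.83 and 108 ± 120) and Igfbp3, which was outside the naming rule and is given because DESeq2 called it (79.8 ± 43.9 and 606 ± 783; log2 fold change 2.10, SE 0.74). Igfbp3 had 1508 CPM in SHR replicate 3 and 94.1 to 217 CPM in the other SHR libraries, which overlapped those of WKY. Igf1 reached 246 CPM in SHR replicate 3 and 30.7 to 46.7 CPM in the batch 1 SHR libraries. The list as a whole did not pass camera (adjusted p = 0.273).

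Across all 12614 genes tested, 13 were higher and 19 lower in SHR by the edgeR quasi-likelihood test, each by at least 2-fold. The libraries of the strains did not overlap in 29 of these 32 genes. At an unadjusted p below 0.05 there were 1675 genes, against 631 that chance would give. Among all genes tested 9.81% showed no overlap. Chance gives 10% for 3 against 3 libraries that can be exchanged, which the batches do not allow, and the 5 other splits that part the batch 2 libraries gave 2.16% to 4.72%. With the replicate number as a block 2 genes were higher and 4 lower, 5 of which were among the 32. DESeq2 called 379 higher and 351 lower, the 32 among them. Within batch 1 the counts were 11 and 11, with 13 shared. Without SHR replicate 1 and without SHR replicate 2, 0 genes were called by edgeR, with 2 residual degrees of freedom, although 1134 and 1513 had an unadjusted p below 0.05. With any 1 library left out the log2 fold change of Rpl30 lay between 7.36 and 8.10 and that of Car9 between -6.58 and -5.68. Without WKY replicate 1 there were 3 higher and 1 lower, without WKY replicate 2 there were 35 and 30, and without WKY replicate 3 there were 11 and 9.

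The gene with the largest increase in SHR was Rpl30 (gene identifier 64640), a protein of the large ribosomal subunit, with 1.46 ± 0.64 CPM in WKY and 290 ± 38.0 CPM in SHR (SD, n = 3 each). Its log2 fold change was 7.67 (SE 0.39, adjusted p = 0.0155). Its numbered copy, LOC100362027 (Rpl30l2 in current RefSeq), went the other way, from 253 ± 37.3 to 1.86 ± 0.89 CPM. Counts of Rpl30 and this copy added together were 255 ± 36.7 CPM in WKY and 292 ± 38.0 CPM in SHR, a log2 difference of 0.20 (SE 0.13, adjusted p = 0.564). Similarly Hmgb2l1 rose by 3.898 on the log2 scale (SE 0.28, adjusted p = 0.0177), from 7.39 ± 3.04 to 126 ± 78.3 CPM, while Hmgb2, the chromatin protein gene it is named after, fell by 2.53 on the log2 scale (SE 0.22, adjusted p = 0.0216), from 105 ± 76.3 to 17.7 ± 13.9 CPM. The sum of this pair was 112 ± 79.3 and 144 ± 90.4 CPM (log2 difference 0.50, SE 0.17, unadjusted p = 0.0267, adjusted p = 0.322). Values of either member of such pairs are uncertain, because reads of near-identical sequences can be given to either. Among the 32 called genes, 3 of those higher and 4 of those lower belonged to a gene and numbered copy pair, and 2 more were class I histocompatibility genes of the RT1 family.

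**Figure D2:**
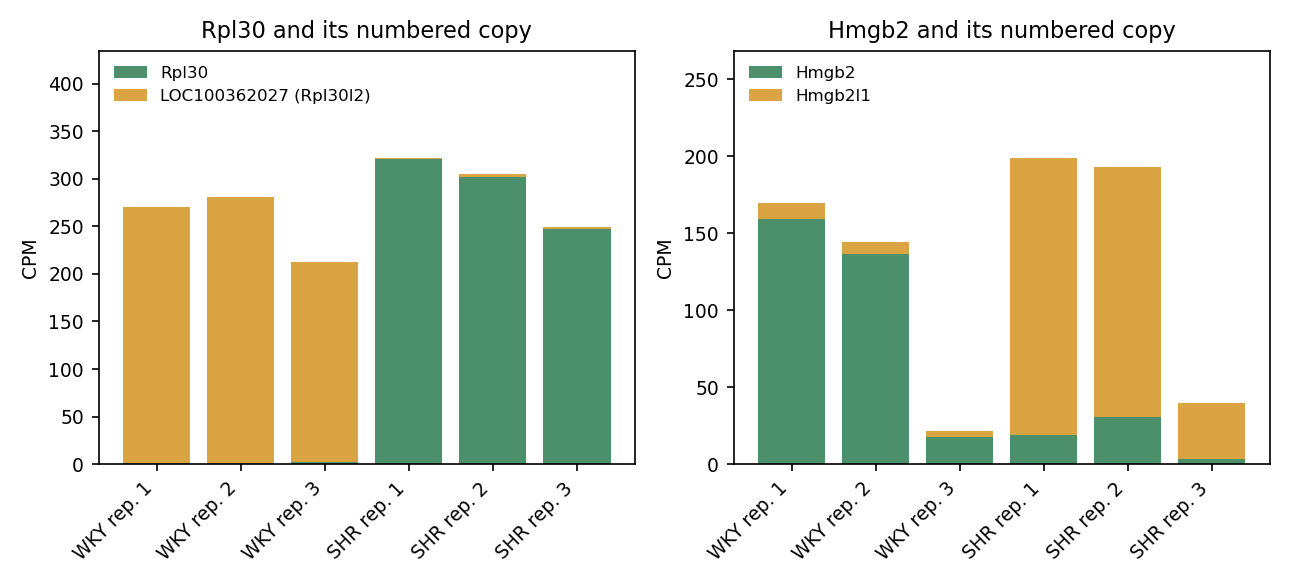
Stacked CPM of Rpl30 with its copy LOC100362027 (left) and of Hmgb2 with its copy Hmgb2l1 (right) in each of the 6 libraries. The sum of Rpl30 and its copy was 255 CPM on average in WKY and 292 CPM in SHR, while the member that held the counts differed between the strains.

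Among the other named genes higher in SHR, Mreg, which encodes melanoregulin, had 0.56 ± 0.34 CPM in WKY and 14.4 ± 7.88 in SHR, a log2 fold change of 4.71 (SE 0.32, adjusted p = 0.0177). Fmo1, a flavin-containing monooxygenase, had 4.21 ± 5.72 and 54.5 ± 50.5 CPM, with its highest level (113 CPM) in the batch 2 SHR library. Mettl2b, a transfer RNA methyltransferase, had 2.04 ± 0.79 and 15.7 ± 7.90 CPM. The adhesion molecule gene Lsamp had 23.7 ± 22.0 and 166 ± 157 CPM, a log2 fold change of 2.78 (SE 0.20). RT1-CE4, a class I histocompatibility gene with many close relatives that can share its reads, had 2.98 ± 0.40 and 17.98 ± 6.33 CPM. With the replicate block, Rpl30 (adjusted p = 0.0455) and Mreg (0.0488) stayed below the threshold, while Fmo1, Hmgb2l1, Mettl2b, Lsamp and RT1-CE4 had adjusted p between 0.0858 and 0.125. Without WKY replicate 1 the adjusted p of these 7 genes lay between 0.0507 and 0.104, without SHR replicate 1 between 0.112 and 0.16, and without SHR replicate 2 between 0.0991 and 0.156. Mettl2b (0.0773), Lsamp (0.0542) and RT1-CE4 (0.0542) were not called without WKY replicate 3, Mettl2b (0.0747) and RT1-CE4 (0.0721) without SHR replicate 3, and Mettl2b (0.0556) without WKY replicate 2.

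The largest decrease among the named genes was that of Car9, a membrane-bound carbonic anhydrase and target of hypoxia-inducible factor, from 292 ± 96.6 CPM in WKY to 6.01 ± 6.16 CPM in SHR (log2 fold change -6.00, SE 0.45, adjusted p = 0.0177). Cd22, a sialic acid-binding lectin best known from B cells, fell from 27.7 ± 5.49 to 1.63 ± 1.56 CPM. Gldn (gliomedin) fell from 15.97 ± 13.6 to 0.99 ± 0.91 CPM, and Atp11b, a phospholipid flippase, from 37.0 ± 3.00 to 3.63 ± 1.38 CPM. Sema7a, a membrane-anchored semaphorin, fell from 30.7 ± 8.34 to 3.16 ± 0.72 CPM (log2 fold change -3.28, SE 0.21, adjusted p = 0.0177). Icoslg, the ligand of a T cell costimulatory receptor, had 20.1 ± 4.59 and 2.29 ± 0.54 CPM. Spopl, an adaptor of a ubiquitin ligase, had 39.1 ± 10.6 and 4.90 ± 0.56 CPM, and Plekhg4, a guanine nucleotide exchange factor, 14.3 ± 5.01 and 2.16 ± 0.70 CPM. With the replicate block Gldn (adjusted p = 0.0488) and Sema7a (0.0455) stayed below the threshold, and the other 6 had adjusted p between 0.0858 and 0.132. Without WKY replicate 1 the adjusted p of these 8 genes lay between 0.0507 and 0.101, without SHR replicate 1 between 0.112 and 0.285, and without SHR replicate 2 between 0.115 and 0.187. Gldn (0.0773), Sema7a (0.0542), Icoslg (0.0894) and Plekhg4 (0.0773) were not called without WKY replicate 3, and Icoslg (0.0747) without SHR replicate 3. The fatty acid transporter gene Cd36, included as a strain check, had 185 ± 202 CPM in WKY and 145 ± 133 CPM in SHR and was not called (log2 fold change -0.15, SE 0.30, adjusted p = 0.863); in batch 1 its difference was 0.02.

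**Figure D3:**
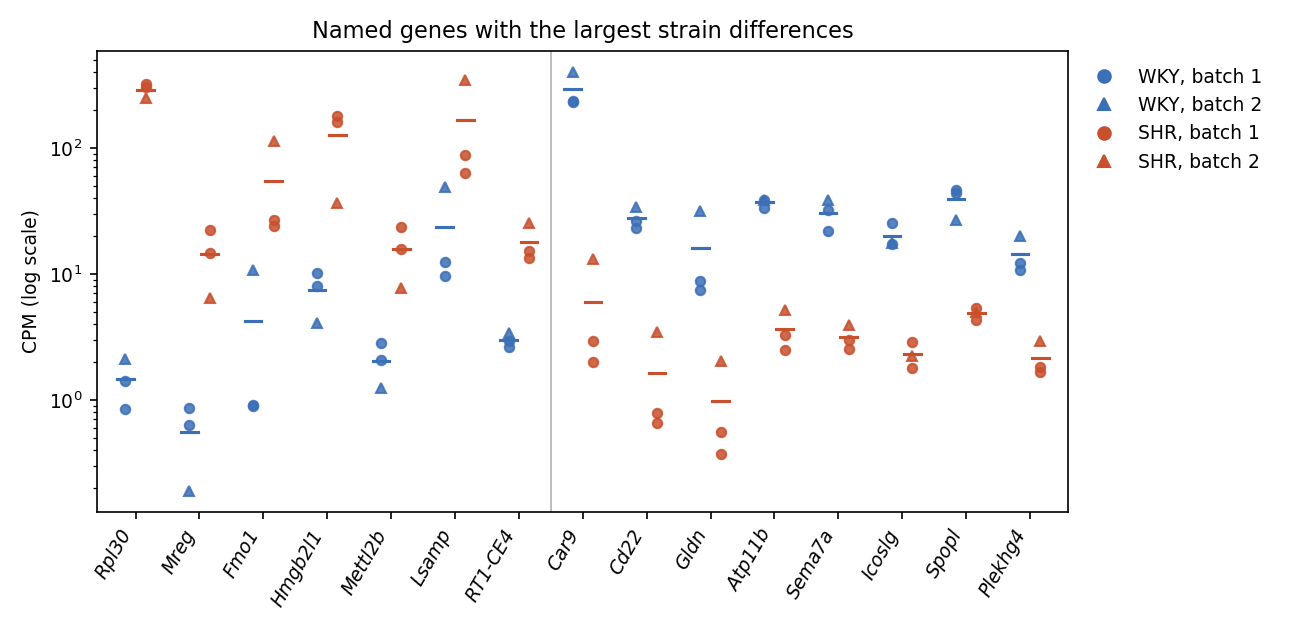
Levels in CPM on a log axis of the 7 named genes higher in SHR (left of the line) and the 8 named genes lower in SHR (right of it), for each library; circles are batch 1, triangles batch 2, and horizontal bars strain means. The libraries of the strains do not overlap in any of the 15, which the naming rule required, and Car9 falls from a mean of 292 CPM in WKY to 6.01 CPM in SHR.

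Of the 24 gene lists tested, the fibroblast and proliferation lists passed camera, both higher in SHR. In the fibroblast list 16 of 20 measured members had a positive log2 fold change, with a median of 0.82 (camera adjusted p = 9.48e-06, and adjusted p = 0.672 with an estimated correlation). Only Tcf21, a transcription factor of adventitial and cardiac fibroblasts, was called by edgeR over all genes, and 8 members rose adjusted over the list alone. DESeq2 called the same 8 higher, and these and Col3a1 had an unadjusted p below 0.05. Tcf21 was called in the full set and without WKY replicate 2; its adjusted p was 0.0974 without WKY replicate 1, 0.128 without WKY replicate 3, 0.197, 0.187 and 0.219 without SHR replicate 1, 2 and 3, and 0.132 with the replicate block. It had 0.06 ± 0.06 CPM in WKY, from 3 counts in all, and 8.78 ± 13.2 CPM in SHR, with 24.0 CPM in the batch 2 library and 1.17 to 1.21 CPM in batch 1. Lum, a small collagen-binding proteoglycan, had 38.5 ± 27.3 CPM in WKY and 286 ± 275 in SHR (log2 fold change 2.69, SE 0.38, adjusted p = 0.0961, and 0.00469 adjusted over the list alone). Dpt, the matrix protein dermatopontin, had 0.30 ± 0.38 and 27.97 ± 13.64 CPM and was called by edgeR when WKY replicate 2 was left out (adjusted p = 0.0411), and the transcription factor Twist2 had 14.0 ± 5.38 and 29.0 ± 4.09 CPM. Libraries of the strains did not overlap in 9 of the 20 members. SHR replicate 3 held the highest levels of several, as of Lum (599 CPM against 85.8 and 172 in the other SHR libraries) and, chosen after their values were seen, of Gsn (11357 against 1459 and 2600), Dcn (1307 against 245 and 386) and Dpp4 (432 against 18.3 and 23.9). Without that library the list passed with a median of 0.79 (adjusted p = 6.97e-05, and 0.775 with an estimated correlation). That fit compares the strains within batch 1 only.

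In the proliferation list 25 of 29 cell cycle genes had a positive log2 fold change, with a median of 0.34 (camera adjusted p = 8.85e-06, and adjusted p = 0.672 with an estimated correlation). No member was called by edgeR, over all genes or adjusted over the list alone; 12 were higher and 1 lower at an unadjusted p below 0.05, and DESeq2 called 3 higher and 1 lower. Birc5, the mitotic gene of survivin, had 18.7 ± 14.2 CPM in WKY and 32.1 ± 25.1 in SHR, and the mitotic kinesin gene Kif20a had 76.3 ± 45.8 and 120 ± 79.1 CPM. Tyms, the thymidylate synthase gene, went the other way, with 56.0 ± 22.2 and 31.5 ± 16.8 CPM. All 29 members were lower in the batch 2 libraries than in batch 1 by edgeR. Without the batch term the list did not pass (adjusted p = 0.259).

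Senescence was addressed with a list of cell cycle inhibitors, p53 targets and nuclear proteins. Of its 16 members edgeR called 1 over all genes, Hmgb2, which fell as described with its copy and is therefore uncertain. Its adjusted p was 0.0858 with the replicate block, 0.0782 without WKY replicate 1, 0.0812 without WKY replicate 3, and 0.112, 0.134 and 0.0747 without SHR replicate 1, 2 and 3. Adjusted over the list alone, 3 rose and 5 fell. Those that rose were the cyclin-dependent kinase inhibitor genes Cdkn2c (23.0 ± 14.7 CPM in WKY and 45.3 ± 22.7 in SHR) and Cdkn1c (1.47 ± 1.15 and 13.5 ± 10.3; called over all genes without WKY replicate 2, adjusted p = 0.0411), and Lmnb1, the lamin B1 gene. Those that fell besides Hmgb2 were Gadd45a, Tp53inp1, and the inhibitor genes Cdkn2a (75.3 ± 54.7 and 25.1 ± 4.6) and Cdkn2b (100 ± 32.6 and 50.1 ± 8.96). DESeq2 called Cdkn2c and Cdkn1c higher, and Hmgb2, Gadd45a, Cdkn2a and Cdkn2b lower. All members that rose or fell adjusted over the list alone had an unadjusted p below 0.05, as did Cdkn1b, which was higher. Cdkn1b, Cdkn1c, Lmnb1, Tp53inp1 and Cdkn2a lie outside the naming rule and were chosen after their values were seen. Cdkn1a, the p21 gene, also outside the rule, had 263 ± 119 and 217 ± 49.2 CPM and was not called. The list did not pass camera (adjusted p = 0.389). Camera asks for a shift of the members in 1 direction, and this list joins genes that need not move together. Its result therefore does not decide whether senescence differed between the strains.

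Secreted factors of senescent cells did not pass camera either (adjusted p = 0.368). Of 16 members 0 were called over all genes, 1 was higher and 2 lower at an unadjusted p below 0.05, and DESeq2 called 1. This was Tgfb1, which fell adjusted over the list alone, with 150 ± 81.3 CPM in WKY and 70.9 ± 41.2 CPM in SHR (log2 fold change -1.10, SE 0.14, adjusted p = 0.069). The median log2 fold change was -0.68 and became -0.20 without WKY replicate 1. That library held 335 CPM of the chemokine transcript Cxcl1 and 599 CPM of Ccl2, against at most 8.3 and 43.4 CPM in any other library. In the endothelial activation list, which shares these chemokines, 0 of 16 members were called by edgeR or DESeq2 and 0 had an unadjusted p below 0.05. Its median log2 fold change was -0.23 (camera adjusted p = 0.697). Without WKY replicate 1 the median was 0.27 and the list was higher in SHR (adjusted p = 0.00624, and adjusted p = 0.579 with an estimated correlation). The median was -0.45 without WKY replicate 2, -0.51 without WKY replicate 3 or SHR replicate 3, -0.15 without SHR replicate 1 and -0.10 without SHR replicate 2.

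Among matrix genes, Lama5, a chain of basement membrane laminin, had 326 ± 240 CPM in WKY and 88.0 ± 33.9 in SHR and was the member of the extracellular matrix list that fell adjusted over the list alone (log2 fold change -1.72, SE 0.23, adjusted p = 0.0778). None of the 31 members was called over all genes, 1 was higher and 4 lower at an unadjusted p below 0.05, DESeq2 called 1 higher and 1 lower, and the list did not pass (adjusted p = 0.381). In the matrix protease list the aggrecanase genes Adamts9 (27.0 ± 10.6 and 65.1 ± 15.7 CPM) and Adamts5 (10.8 ± 5.08 and 27.7 ± 9.68 CPM) rose adjusted over the list alone, and 0 of 17 were called over all genes, with 5 higher and 1 lower at an unadjusted p below 0.05 and 4 higher by DESeq2. This list also holds protease inhibitors. Of these Timp3 (25.4 ± 32.8 CPM in WKY and 96.4 ± 136.8 in SHR) is among the higher genes in both counts. The protease list did not pass (adjusted p = 0.0516), but passed without WKY replicate 1 (0.00624), without WKY replicate 2 (0.0229) and without SHR replicate 2 (0.0131). With an estimated correlation the adjusted p in these fits lay between 0.559 and 0.645. In the endothelial to mesenchymal transition list 0 of 16 were called, 2 were higher and 5 lower at an unadjusted p below 0.05, DESeq2 called 1 higher and 3 lower, and Tgfb1 fell adjusted over the list alone. Fn1, the fibronectin gene, had 5759 ± 4507 and 1545 ± 405 CPM, and the list did not pass (adjusted p = 0.549).

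The smooth muscle list had a median log2 fold change of -0.43 (camera adjusted p = 0.0516), with 14 of 18 members negative; it passed without WKY replicate 1 (0.00216, and adjusted p = 0.579 with an estimated correlation) and without SHR replicate 1 (0.00906, and 0.674 with an estimated correlation). The median was -0.80 without WKY replicate 1, -0.11 without WKY replicate 3 and -0.10 without SHR replicate 3. Adjusted over the list alone 2 fell, the integrin gene Itga8 (380 ± 233 CPM in WKY and 130 ± 61.9 in SHR) and Myocd, the gene of the smooth muscle coactivator myocardin (32.7 ± 42.1 and 7.26 ± 6.23); DESeq2 called 2 lower, 4 were lower at an unadjusted p below 0.05, and 0 were called by edgeR over all genes. The Notch and arterial identity list had a median of -0.64 (adjusted p = 0.0637, and without WKY replicate 2 0.0229, or 0.645 with an estimated correlation), with 0 of 14 called by edgeR, 2 higher and 4 lower at an unadjusted p below 0.05, and 2 lower by DESeq2. The netrin receptor gene Unc5b had 437 ± 204 and 186 ± 67.8 CPM, and the gap junction gene Gja5 had 478 ± 225 and 175 ± 176 CPM. Pericyte genes had a median of -1.02 (adjusted p = 0.273), with 0 of 7 called by edgeR or DESeq2 and 0 at an unadjusted p below 0.05. For vasoactive genes the adjusted p was 0.373, with 0 of 24 called by edgeR, 3 higher and 2 lower at an unadjusted p below 0.05 and 2 lower by DESeq2. Shear response genes gave 0.273, with Sema7a called among 10, and BMP signalling genes 0.389, with 0 of 15 called by edgeR, 3 lower at an unadjusted p below 0.05 and 1 lower by DESeq2.

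In the hypoxia and glycolysis list 15 of 17 members had a negative log2 fold change, with a median of -0.26 (adjusted p = 0.0516, and without WKY replicate 2 0.0499, or 0.645 with an estimated correlation). The median was -0.16 without WKY replicate 1 and -0.11 without WKY replicate 3 or SHR replicate 3. Car9 was the member called, and none of the others passed adjusted over the list alone. Glycolytic and hypoxia genes such as Pfkp (54.55 ± 15.99 CPM in WKY and 40.9 ± 3.22 in SHR) and Pdk1 (24.0 ± 1.41 and 20.1 ± 3.92) differed by far less than Car9. Cholesterol synthesis genes had a median of -0.38 (adjusted p = 0.0516), with 16 of 18 negative. None was called by edgeR over all genes, 1 was lower at an unadjusted p below 0.05, and DESeq2 called 1 lower. The list passed without WKY replicate 1 (0.00262), SHR replicate 1 (0.0366) and SHR replicate 2 (0.00687), with adjusted p between 0.618 and 0.827 with an estimated correlation. The median was -0.67 without WKY replicate 1, -0.60 without WKY replicate 2 and -0.64 without SHR replicate 2. Within batch 1 the median was 0.20 and the list pointed up (adjusted p = 0.235). Leaving out WKY replicate 3 or SHR replicate 3 makes the same comparison within batch 1, and also gave 0.20. Lss, the lanosterol synthase gene, had 150 ± 1.78 CPM in WKY and 47.4 ± 22.7 in SHR and fell adjusted over the list alone (log2 fold change -1.80, SE 0.33, adjusted p = 0.144). With median-of-ratios factors the smooth muscle, matrix protease, hypoxia and glycolysis and cholesterol synthesis lists each passed at an adjusted p of 0.0457, and the Notch and arterial identity list at 0.0495, with adjusted p between 0.688 and 0.735 with an estimated correlation. With an estimated correlation 0 of the 24 lists passed, and 0 had an unadjusted p below 0.05.

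Antigen presentation genes moved both ways, with 3 rising and 3 falling adjusted over the list alone and 0 of 13 called over all genes, while 3 were higher and 3 lower at an unadjusted p below 0.05 and DESeq2 called 2 higher and 3 lower (camera adjusted p = 0.82). Psmb8, an immunoproteasome subunit, had 11.0 ± 5.37 CPM in WKY and 34.6 ± 9.26 in SHR (log2 fold change 1.70, SE 0.25, adjusted p = 0.0961, and 0.0411 without WKY replicate 2). The class I genes RT1-A1 (71.2 ± 26.6 and 268 ± 65.0 CPM) and RT1-CE5 (110 ± 22.5 and 44.9 ± 20.2 CPM) went in opposite directions, and reads of this gene family can be given to more than 1 member. Oxidative stress genes gave an adjusted p of 0.936, with the superoxide dismutase gene Sod1 (127 ± 22.6 and 219 ± 46.0 CPM) rising adjusted over the list alone. The immediate early and heat shock list, a check of handling, gave 0.389, with Egr1 rising adjusted over the list alone. Interferon response (0.389), unfolded protein response (0.132) and strain genes (0.82) did not pass, though the unfolded protein response list did without WKY replicate 2 (0.0427) and without SHR replicate 2 (0.0394), lower in SHR (0.645 and 0.654 with an estimated correlation). No member of these 5 lists was called by edgeR over all genes. At an unadjusted p below 0.05, 2 oxidative stress genes were higher and 3 lower, 2 immediate early and heat shock genes higher and 1 lower, 2 interferon response genes higher, 3 unfolded protein response genes lower, and 1 strain gene higher and 1 lower. DESeq2 called 2 higher and 1 lower, 1 higher, 1 higher, 1 lower and 1 lower of these lists in the same order.

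Most endothelial markers had low levels in all 6 libraries. Pecam1 and Cdh5, the endothelial adhesion genes, had 79 and 4 counts over all 6 libraries, and the receptor gene Kdr and the clotting factor gene Vwf had 33 and 58. Pecam1 had 0.25 ± 0.17 CPM in WKY and 1.14 ± 0.92 in SHR (SD, n = 3 each). Of 26 endothelial identity genes in the table, 4 reached a mean of 10 CPM, and 11 had enough counts to be tested. The 4 were Eng, a co-receptor of TGF-beta (119 to 635 CPM), the receptor gene Flt1 (7.03 to 79.3 CPM), Egfl7 (6.39 to 27.2 CPM) and Mcam (0.79 to 47.8 CPM). Among the tested genes Tek, an angiopoietin receptor, rose (0.98 ± 0.76 and 7.47 ± 2.44 CPM) and Mcam fell (18.3 ± 25.5 and 3.78 ± 4.28 CPM) adjusted over the list alone, 0 were called over all genes, 2 were higher and 2 lower at an unadjusted p below 0.05, and DESeq2 called 2 higher and 1 lower. The list did not pass camera (adjusted p = 0.819). By contrast 13 of 20 fibroblast genes exceeded 50 CPM on average, and the collagen gene Col1a1 had 6888 ± 3611 CPM in WKY and 6954 ± 2168 in SHR. The smooth muscle gene Acta2 had 1276 ± 2038 CPM in WKY and 353 ± 328 in SHR, with the highest level, 3630 CPM, in the batch 2 WKY library. In batch 1 its levels were lower in WKY (93.5 and 105 CPM) than in SHR (144 and 184 CPM).

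**Figure D4:**
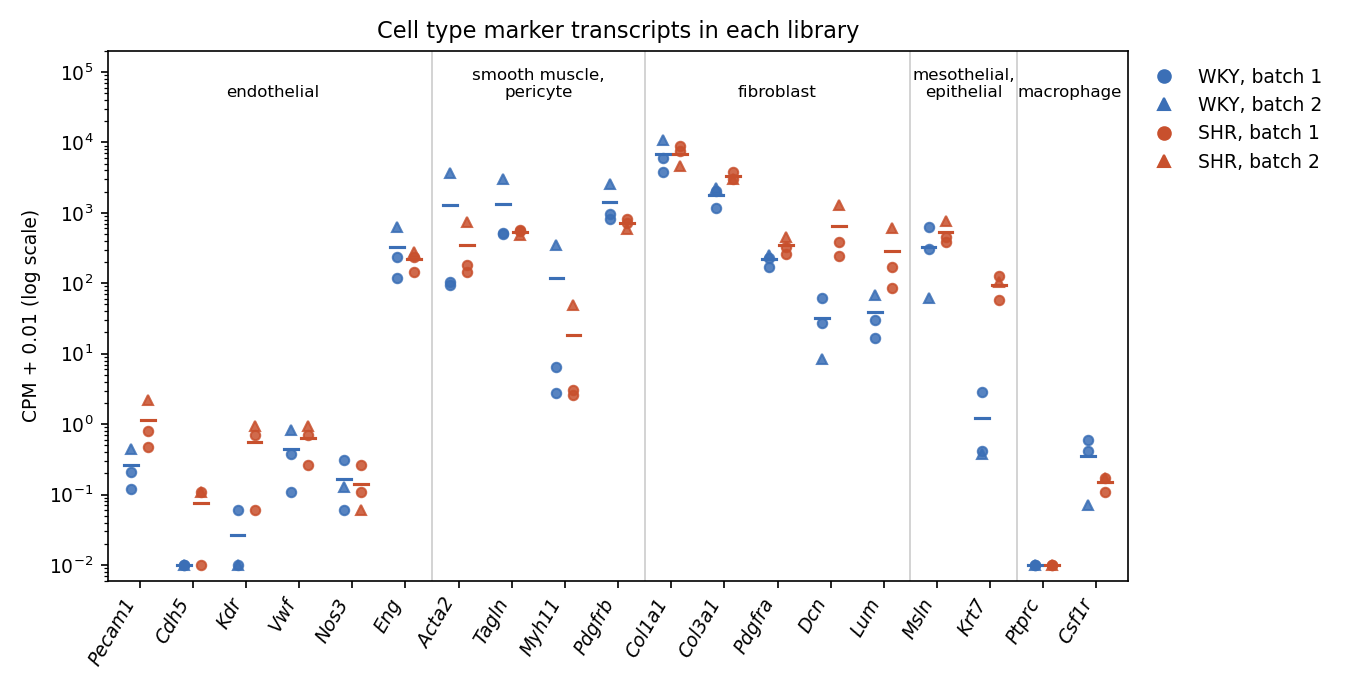
Levels of cell type marker transcripts in each library, in CPM plus 0.01 on a log axis; circles are batch 1, triangles batch 2, and horizontal bars strain means. Pecam1 stayed at or below 2.18 CPM in all 6 libraries, while Col1a1 lay between 3846 and 10878 CPM.

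Other cell type lists had too few measured members for camera. The mesothelial gene Msln was abundant in both strains (61.3 to 758 CPM). Krt7, a keratin of simple epithelia and mesothelium, had 1.2 ± 1.4 CPM in WKY and 95.7 ± 35.6 in SHR; it missed the threshold over all genes (log2 fold change 6.36, SE 0.90, adjusted p = 0.103, and 0.0411 without WKY replicate 2) and rose adjusted over the list alone (0.00297), as 1 of 4 tested mesothelial and epithelial genes. DESeq2 called it (adjusted p = 3.52e-08). The mesothelial gene Upk3b had 2.23 ± 2.62 and 63.1 ± 89.8 CPM (unadjusted p = 0.0386, adjusted p = 0.358), with 166 CPM in SHR replicate 3, 23.4 in SHR replicate 2 and 0.05 in SHR replicate 1. Lrrn4 (0.24 ± 0.17 and 36.4 ± 58.1 CPM), Bnc1 (0.08 ± 0.10 and 8.86 ± 14.1 CPM) and Muc16 (0 counts in WKY and 218 in SHR), which were not tested, and the mesothelial transcription factor gene Wt1 (2.17 ± 1.83 and 11.8 ± 16.4 CPM, not called) also had their highest level in SHR replicate 3. Lipe, a lipase gene of adipocytes, had 0.27 ± 0.15 and 4.67 ± 5.32 CPM, with 10.8 CPM in SHR replicate 3 and 1.58 to 1.63 in the other SHR libraries. It was not called over all genes (adjusted p = 0.187), rose adjusted over the list alone among 2 tested adipocyte genes, and was called by DESeq2 (adjusted p = 0.000766). No chondrocyte gene was called by edgeR over all genes or by DESeq2. All 3 tested had an unadjusted p below 0.05 and fell adjusted over the list alone, with Sox9 at 39.6 ± 55.6 CPM in WKY and 14.9 ± 18.4 in SHR, Col11a1 at 407 ± 173 and 248 ± 145 CPM, and Comp at 1.34 ± 0.89 and 0.31 ± 0.14 CPM. The glial gene S100b had 3.60 ± 4.02 and 37.0 ± 23.8 CPM and was not called, as 1 of 2 tested Schwann cell genes. Of the leukocyte genes, Ptprc had 0 counts in all 6 libraries, which allows up to 0.027 CPM, and Csf1r had 0.35 ± 0.26 and 0.14 ± 0.03 CPM. Cd14 (14.8 to 39.3 CPM) and Cd68 (3.48 to 28.02 CPM), also of the macrophage list, were present in all 6 libraries. No member was called by edgeR or DESeq2 among the 2 tested macrophage, 3 cardiomyocyte and 4 lymphatic endothelium genes, and 0 of these had an unadjusted p below 0.05. The lymphocyte list had no gene with enough counts to be tested, and no gene of the erythrocyte list was matched.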

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

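Limma on the deposited log2 values, the summing of gene copies and the estimated correlation within each other alternative were added after the data were seen; the other alternatives were planned. The 13 genes higher and 19 lower in SHR, all by at least 2-fold, became 379 and 351 with DESeq2 (259 and 225 by at least 2-fold), 1 and 1 without the batch term, 2 and 4 with the replicate block, 11 and 11 in batch 1 alone, and 117 and 111 with limma on the deposited values (28 and 25 by at least 2-fold). The 2-fold counts equalled the full counts in the edgeR fits named here. DESeq2 called all 32 genes, limma on the deposited values 30, limma-voom 26, batch 1 alone 13, the replicate block 5 and the fit without batch 2. In simulated data 26.0% of DESeq2 calls and 7.87% of edgeR calls were false; why the real counts differ by more than in simulated data was not tested. Without the batch term the batch difference enters the spread, and batch 1 alone leaves 4 libraries. Leaving out a batch 2 library also leaves only batch 1 to compare the strains. Limma on the deposited values had strain as its only term. The batch difference already removed from those values was not counted as a term, so its p-values can come out too small. With median-of-ratios factors, upper-quartile factors, no low-count filter, the stricter filter, limma-voom or no robust dispersion the counts lay between 14 and 18 higher and 19 and 23 lower. Scaling moved the median log2 fold change by at most 0.025. Leaving out each library in turn gave 0 to 35 higher and 0 to 30 lower genes, with the same range for those of at least 2-fold; the 0 came without SHR replicate 1 or SHR replicate 2 and the most without WKY replicate 2. Summing copies gave 9 and 14. Igfbp6 was called by DESeq2 (log2 fold change 1.41, adjusted p = 0.0414) and by no other fit, with log2 fold changes between 1.01 and 1.55 in the other fits of all libraries or of batch 1, and between 1.04 and 2.05 with a library left out (adjusted p between 0.115 and 0.611). The cause was not tested. The 2 lists that passed became 7 with median-of-ratios and with upper-quartile factors. They became 6 with no low-count filter and with limma-voom, and 4 without the batch term. With an estimated correlation, and with the directional test of fry, which asks another question, 0 passed. At an unadjusted p below 0.05 there were 8 in the planned test, 0 with the estimated correlation and 6 with directional fry. The mixed test of fry asks whether members moved in either direction. It passed 11 lists after adjustment, and 13 had an unadjusted p below 0.05. The estimated correlation widens the null of each list by construction, and the other causes were not tested. With a library left out 2 to 8 lists passed, among them lists that reached 5 measured members only there, through genes seen mostly in 1 strain. The fibroblast list passed in each of these (adjusted p between 5.87e-07 and 0.000426), as did the proliferation list (7.37e-08 to 0.00687), and both passed with the replicate block, which changed the call of no list. Some directions turned, with the cause not tested. The endothelial identity list pointed up with no low-count filter (adjusted p = 0.484) and without the batch term (0.77), and also without WKY replicate 1, WKY replicate 2, SHR replicate 1 or SHR replicate 2, with adjusted p between 0.193 and 0.952 when a library was left out. The endothelial activation list pointed up without WKY replicate 1 or SHR replicate 2, over a range of 0.00624 to 0.979. The cholesterol synthesis list pointed up in batch 1 alone (0.235) and without either batch 2 library, which is the same comparison. Its adjusted p lay between 0.00262 and 0.254 when a library was left out. Cd36 turned to 0.023 in batch 1 alone and ranged from -0.509 to 0.046 with a library left out; Cxcl1 ranged from -4.599 to 0.264 and Tlr2 from -3.441 to 0.141, both positive without WKY replicate 1. Acta2, given by its levels only, turned to 0.091 with limma-voom and 0.72 in batch 1 alone, and ranged from -0.71 to 0.725 with a library left out. Msln and Wt1, also given by their levels, turned to -0.154 and -0.496 in batch 1 alone and ranged from -0.149 to 1.669 and from -0.49 to 3.024 with a library left out. The correction for GC content and gene length was not run, since no genome of the build was used here. In data simulated from the means and dispersions of these 6 libraries, edgeR recovered 23.6% of the genes changed 2-fold.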

Other observations

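The split of the 6 libraries was planned; the other tests below were chosen after the values were seen. Batch 2 differed from batch 1 in more genes than the strains did, in the same edgeR fit: 2654 genes were higher and 2837 lower in batch 2. All 29 cell cycle genes of the proliferation list were lower there, with a median log2 fold change of -2.94 (camera adjusted p = 7.21e-16, and adjusted p = 0.616 with an estimated correlation). Top2a, a topoisomerase of dividing cells, had a mean of 120 CPM in batch 1 and 9.31 CPM in batch 2. Of 18 smooth muscle genes 11 were higher in batch 2 and 0 lower, with a median of 2.43 (camera adjusted p = 0.000524, and adjusted p = 0.732 with an estimated correlation). Acta2 had 132 CPM in batch 1 and 2180 CPM in batch 2, and the smooth muscle myosin gene Myh11 had 3.68 and 197 CPM. The endothelial to mesenchymal transition, Notch and arterial identity, and strain gene lists were also higher in batch 2 (adjusted p between 0.0204 and 0.021, and 0.616 with an estimated correlation). Batch 2 has 1 library of each strain, and the labels do not say how the batches differed.

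With 32 genes called between the strains, the highest of the other 9 ways to split the 6 libraries into 3 and 3 gave 4, and 1 of the 10 splits, the real one, gave as many. With 10 splits the share cannot go below 0.1, which is too few to decide whether chance is excluded. Only 5 of the other splits part the batch 2 libraries as the strains do, so within batches the limit is higher still. The split with 4 genes put both batch 2 libraries together; the 3 other splits that part all 3 same-numbered pairs gave 0.

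Rpl30 and Hmgb2 moved against their numbered copies. The summed Rpl30 counts differed by 0.20 on the log2 scale (SE 0.13), consistent with the hypothesis that reads of 1 transcript were given to different copies in the strains, as a strain variant against the reference would do. For Hmgb2 the sum differed by 0.50 (SE 0.17), too close to the bound of 0.5 to decide. For Ndufa10, Diablo and Uap1 the gene was asked to change oppositely by 0.5 to 2 times the change of its copy. Of the 3 pairs 1, Diablo, lay in this range, which was set after the values were seen. Ndufa10 fell by 2.22 times the rise of its copy, from 90.1 ± 1.24 CPM in WKY to 60.3 ± 6.04 in SHR. Uap1 cannot decide, since it had 297 ± 196 and 396 ± 370 CPM and its copy 7.1 ± 4.31 CPM in WKY. In the Rpl30 and Hmgb2 pairs the member that moved less moved by 7.08 (SE 0.38) and 2.53 (SE 0.22) on the log2 scale. This cannot decide whether the transcription of a single copy changed with the other unchanged. The pairs were picked because both members moved, and reads of 1 member can be given to the other. A strain difference that moved both copies stays open.

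Most endothelial transcripts were scarce in all 6 libraries, with 4 of 26 at a mean of 10 CPM or more and Eng at 119 to 635 CPM. Depth is argued against, since 3 counts were worth at most 0.19 CPM in any library. The highest level of Pecam1 or Cdh5 in any library was 2.2 CPM while 13 of 20 fibroblast genes exceeded 50 CPM, consistent with the hypothesis that most cells in the cultures were not endothelial; Col1a1 lay between 3846 and 10878 CPM. Smooth muscle and mesothelial transcripts were present as well, and fibroblast genes such as Col1a1 are also expressed by smooth muscle cells, so the markers do not name a single cell type. That endothelial cells lost their transcripts in culture and took on mesenchymal ones cannot be told apart from this, because 0 libraries of uncultured cells were analysed.

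WKY replicate 1 held high levels of inflammatory transcripts: Cxcl1 at 334.8 CPM, Ccl2 at 599.2, Ccl7 at 342.4, the protease gene Mmp3 at 79.0, Tlr2 at 117.1 and the mitochondrial superoxide dismutase gene Sod2 at 688.2, from 8.68 to 40.5 times the highest of the other libraries. Leukocytes are argued against, since the highest of 7 leukocyte genes there had 0.45 CPM. These were Ptprc, Csf1r, Tyrobp, Fcer1g, Laptm5, Aif1 and Lck. The macrophage list members Cd14 and Cd68, outside this check, had 35.85 and 19.39 CPM there, and 39.3 and 28.02 CPM in SHR replicate 3. The median log2 fold change of these 6 genes was -2.43 with that library and 0.14 without it (-0.38 to 1.26). The other WKY libraries thus did not share the high levels. Since the genes were picked for standing out in that library, these values are no separate test of a strain difference. Handling stress stays open: the median ratio of 6 immediate early genes to WKY replicate 2 was 1.29, with Junb at 2.24, Fos at 1.91 and Fosb at 1.72 but Ier2 at 0.866, Egr1 at 0.80 and Jun at 0.594. An inflammatory state of that culture or animal was not tested.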
